A study of Mus musculus with 12 samples.

How the data were processed

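Primary mouse embryonic fibroblasts (cells grown from embryos and used before they become a cell line) were prepared from wild-type mice and from mice lacking HtrA2, a serine protease of the mitochondrial intermembrane space also known as Omi. Per the labels' protocols, cells at passage 4 received either vehicle or 1 µM rotenone, an inhibitor of respiratory complex I that also binds tubulin, for 4 h. RNA was purified on columns, converted to biotin-labelled cRNA and hybridised to Affymetrix expression arrays. The 12 arrays fall into 4 groups of 3: wild type with vehicle, wild type with rotenone, knockout with vehicle and knockout with rotenone. The genotype entry of the 3 wild-type rotenone arrays reads knockout, whereas their titles, sources and descriptions read wild type. They were grouped as wild type, and the level of Htra2 on them was used as a check.

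The deposited values are on a log2 scale and were made by the authors with RMA, per the submitters' processing notes; its version and settings are not given in the sources used here. RMA usually removes background, brings the distributions of the arrays together and summarises the probes of a probe set by median polish. Such processing compresses differences near background, and it would hide a change shared by most transcripts. The values ran from 3.19 to 14.59, and the array medians from 7.53 to 7.58. No detection calls or scanner intensities were used here, so the signal over background of single probe sets is unknown and the number of arrays limits the precision. No further normalization was applied.

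The values covered 22690 probe sets, of which 64 array controls were left out and 22626 were tested. The platform annotation gave 1 gene symbol to 20380 of the tested probe sets, several to 691 and none to 1555. Of the probe sets with 1 symbol, 20351 matched a gene in the RefSeq table of assembly GRCm38.p6, and no symbol needed changing. The build behind the array annotation is not given in the sources used here, so that table served only for gene names and for which genes neighbour each other. Each of 12393 genes was represented by its probe set with the highest mean over the 12 arrays; 4956 of these genes had more than 1 probe set.

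Differences were tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, in 1 fit of 4 group means over all 12 arrays. Adjusted p-values are Benjamini-Hochberg values over the 22626 probe sets, and the threshold was 0.05. Except where another tool is named, every adjusted p of a gene comes from this limma fit or from the same fit with the replicate number as a block. The comparisons were knockout against wild type in vehicle and in rotenone, rotenone against vehicle in each genotype, the mean of these rotenone effects, and their difference between genotypes (the interaction). Nothing in the labels says that the replicates came from separate embryos or cultures. The p-values therefore measure only the spread between these samples, which may be technical.

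The labels number the replicates 1 to 3 in every group, and the planned fit had no block. Whether the numbers pair the arrays was checked from the correlation, across probe sets, of each array's deviations from its group mean. All 18 same-numbered pairs correlated, with r from 0.289 to 0.829, and 11 of the 12 arrays had their best partner among arrays of their own number. Arrays numbered 3 stood apart in every group, so deviations from a group mean link arrays 1 and 2 whether paired or not. Within numbers 1 and 2, r ran from 0.289 to 0.554. Between an array 1 and an array 2 of different groups it ran from -0.053 to 0.476. The values thus set number 3 apart clearly, and number 1 from number 2 only weakly. With this limit the numbers were taken to pair the arrays, on the evidence of the data and not of the labels. Results with the number as a block are printed wherever they alter a call or move a count by over 1.5 times. No 2 arrays held identical values; between-array correlations ran from 0.982 to 0.997.

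Before the data were examined, 41 gene lists with 901 entries were fixed. They covered stress responses, mitochondrial complexes, metabolism, cell cycle, cytoskeleton, matrix, genes near Htra2, positional genes and markers of other cell types. Of their entries, 794 were measured and 107 were not named on the arrays. The 39 lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, were run as alternatives. Counts of list members past the threshold are given over all probe sets and adjusted over the list alone.

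Genes named in the text follow a rule that was also written before the data were examined. In the rotenone and vehicle genotype comparisons it takes the 10 largest rises and 10 largest falls among genes past the threshold whose arrays did not overlap between the groups compared. For the mean rotenone effect, this overlap was judged within each genotype. The 5 largest rises and falls apply to the genotype comparison in rotenone and, with no overlap condition, to the interaction. Where fewer than 3 genes passed, the 5 with the smallest p are given. Up to 4 members of a list with the smallest p, and Htra2, Ddit3, Atf4, Trib3, Asns and Mthfd2, are added throughout. The rule was applied to the blocked fit after the data had been seen, with all same-numbered pairs moving one way in place of the overlap condition.

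The procedure was tested on simulated arrays with the measured means, replicate effects and spreads, in which 200 of 22626 probe sets were changed. For the mean rotenone effect the fit without a block recovered 65.7%, 95.5% and 100% of changes of 0.5, 1 and 2 on the log2 scale, with 0 false calls. With the block it recovered 89.6%, 100% and 100%, with 11 false among 204 calls. For the rotenone effect in wild-type cells the fit without a block recovered 25.4%, 76.1% and 100%, and in knockout cells 25.4%, 83.6% and 97.0%. In the blocked fit both genotypes had 53.7% recovered at 0.5. A simulated shift of -0.5 in the tubulin list gave an adjusted p of 1.14e-33 with the preset and 0.00286 with the estimated correlation, and 0 other lists were called. The simulated noise was drawn independently for each probe set. False calls of lists whose genes vary together could therefore not show in it, and the preset correlation was not tested in this respect.

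Alternatives planned before the data were examined were leaving out dim probe sets (mean below 7.01, the 40th percentile), a second quantile normalization, median-centring, eBayes with trend and robust options, array weights, the replicate block, only the arrays compared, a 1.5-fold minimum, the mean of a gene's probe sets, and leaving out each array in turn. Added afterwards were replicates 1 and 2 alone, the same alternatives for the blocked counts, and a block for each genotype and number together.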

Results

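Transcript levels were measured on 12 arrays of mouse embryonic fibroblasts, 3 for each combination of genotype (wild type or HtrA2 knockout) and treatment (vehicle or 1 µM rotenone for 4 h). Array medians lay between 7.53 and 7.58 on the log2 scale. The first principal component of the 22626 probe sets held 44.7% of the variance and set the 4 arrays numbered 3 apart from the other 8. Scores of the arrays numbered 3 lay between 22.6 and 30.9, and those of the others between -20.1 and -5.69. This held in all 4 groups, so replicate 3 was balanced over genotype and treatment, but it widened the spread within every group. With treatment and genotype accounted for, 4924 probe sets differed between replicate 3 and replicates 1 and 2, 2641 higher and 2283 lower (limma). Among them were Mmp3, a matrix metalloprotease, 4.36 higher on the log2 scale, Cxcl1, a chemokine, 4.12 higher, Mki67, a proliferation marker, 1.55 higher, and Ddit3, a stress-induced transcription factor, which was lower (-1.85).

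**Figure D1:**
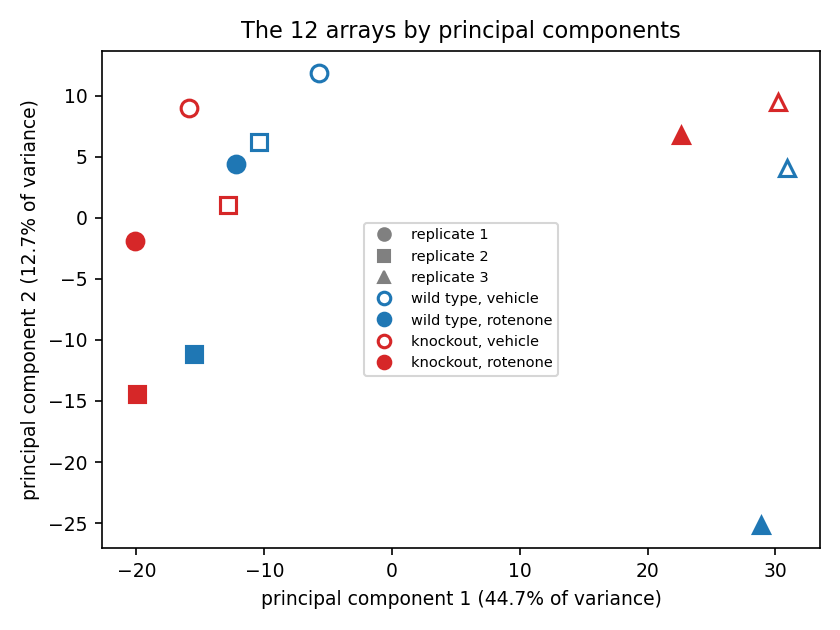
Scores of the 12 arrays on the first 2 principal components of the log2 values, which hold 44.7% and 12.7% of the variance; colours give the group and symbols the replicate number. The 4 arrays numbered 3 lie at 22.6 or above on the first component, and all others at -5.69 or below.

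The targeted gene was examined first. Htra2 was 2.62-fold lower in knockout than in wild-type cells in vehicle (log2 difference -1.39, SE 0.13, limma adjusted p = 0.00320). Its level was 9.06 ± 0.24 in wild-type vehicle, 9.08 ± 0.06 in wild-type rotenone, 7.67 ± 0.17 in knockout vehicle and 7.77 ± 0.09 in knockout rotenone cells (log2, SD, n = 3 each). The lowest wild-type array stood at 8.83 and the highest knockout array at 7.87. All 3 wild-type rotenone arrays, whose genotype entry reads knockout, lay at the wild-type level and were kept as wild type. In rotenone the difference was -1.32 (SE 0.13, adjusted p = 0.00577). A dimmer probe set of Htra2 showed no loss: it was 0.40 higher in knockout vehicle cells (SE 0.17, adjusted p = 1.0), and the mean over both probe sets was -0.50. Which part of the gene was deleted is not given in the labels, so only the brighter probe set served as a check.

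**Figure D2:**
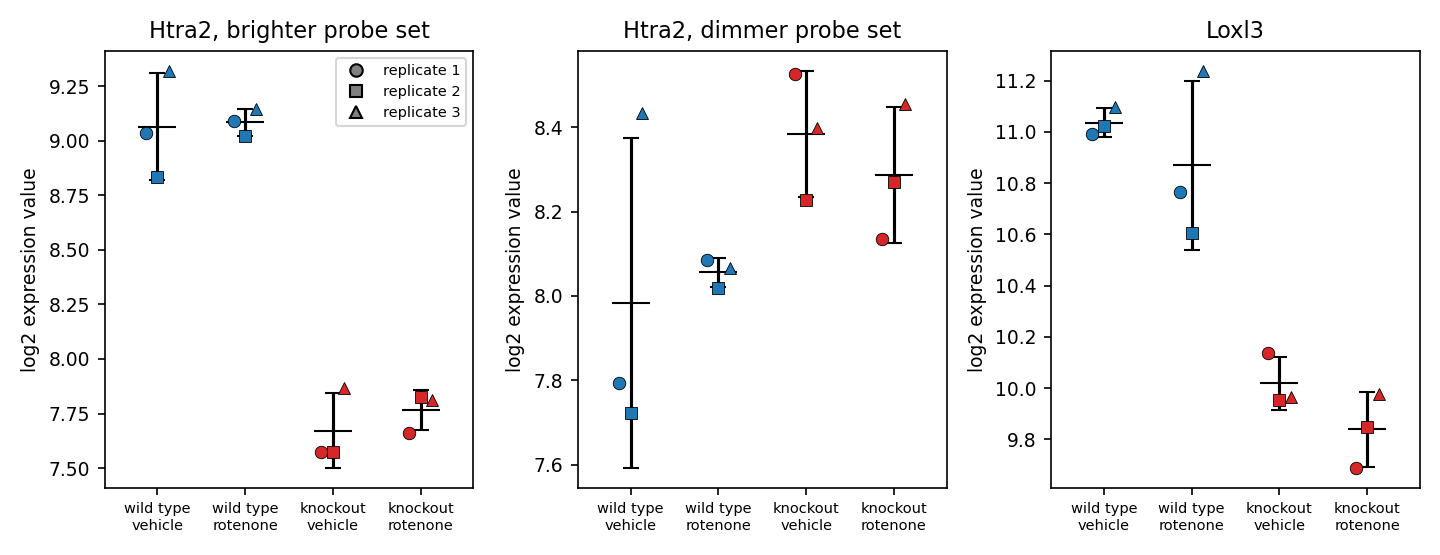
Log2 values of the brighter and the dimmer Htra2 probe set and of Loxl3, a neighbouring gene, on each of the 12 arrays; symbols give the replicate number, and bars the mean and SD of each group (n = 3). On the brighter Htra2 probe set every knockout array lies at 7.87 or below and every wild-type array at 8.83 or above, whereas the dimmer probe set shows no such gap.

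The rotenone response shared by both genotypes was read from the mean of the rotenone effects, 6 treated against 6 vehicle arrays. The deepest fall was that of Txnip, an arrestin-like inhibitor of glucose uptake and thioredoxin, which was 5.33-fold lower with rotenone (log2 difference -2.41, SE 0.19, adjusted p = 4.13e-04). Txnip went from 10.36 ± 0.29 to 8.03 ± 0.54 in wild-type and from 10.37 ± 0.43 to 7.87 ± 0.26 in knockout cells (SD, n = 3). Tubulin transcripts fell next, Tubb3 by 2.58-fold (-1.37), Tubb2a by 2.43-fold (-1.28) and Tubb4b by 2.32-fold (-1.22), and Tubb6 fell by 1.65-fold (-0.72). Among genes passing without the replicate block, Eno2, a glycolytic enolase, rose most (1.77-fold, 0.82). Next came Flcn, which encodes folliculin, a regulator of lysosomal nutrient signalling (1.76-fold, 0.82). Atp6v1b2, a subunit of the proton pump of lysosomes, followed (1.72-fold, 0.78). All genes named in these sentences moved in the stated direction in all 6 same-numbered pairs of arrays. The rule for naming took only genes without overlap within each genotype, so this agreement was largely fixed by their choice.

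In numbers, 49 probe sets passed the threshold for this mean effect, 23 higher and 26 lower, and they stood for 20 higher and 18 lower genes. Unadjusted p-values under 0.05 were found for 1788 probe sets (3393 with the block), where 1131 would be due to chance. Genes passing the rule for naming numbered 14 higher and 13 lower. Besides those above, the 10 largest rises held Stc2, a secreted glycoprotein induced by stress (0.72, SE 0.12, adjusted p = 0.0415), Neu1, a lysosomal sialidase (0.70), Atp6v1c1, another pump subunit (0.59), Ddit4, an inhibitor of mTORC1 signalling (0.52), Ets2 (0.58), Rnf19b (0.58) and Cstf3 (0.53). The 10 largest falls also held Gmppb, which makes GDP-mannose (-0.86, SE 0.12, adjusted p = 0.018), Hmgcs1, an enzyme of sterol synthesis (-0.83), Arf2 (-0.75), and the transcription factors Jun (-0.64) and Klf2 (-0.64). Some further probe sets of these genes moved less or not at all. A second Tubb2a probe set changed by -0.41 (adjusted p = 0.0609) and the dimmest of Flcn rose by 0.40 (0.315). Of 2 further Atp6v1b2 probe sets 1 rose by 0.78 (adjusted p = 0.0415) and the dimmest changed by -0.04, 2 further Neu1 probe sets by 0.07 and 0.03, and 5 further Tubb4b probe sets by -0.24 to 0.11. With the replicate number as a block, 557 probe sets passed, 302 higher and 255 lower, and all 49 were among them; without replicate 1, 2 or 3 the blocked count was 65, 44 or 1054. Leaving out 1 array took the count without a block from 49 to between 7 and 31 for 10 of the 12 arrays, namely all but wild-type rotenone replicate 3 and knockout rotenone replicate 3.

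Several genes of the integrated stress response, the programme led by the transcription factor ATF4, passed only with the block. Trib3, a pseudokinase induced by ATF4, rose 2.13-fold (log2 1.09, SE 0.06 and adjusted p = 6.41e-07 with the block; adjusted p = 0.53 without). Ddit3, which encodes the factor CHOP, rose 1.89-fold with the block (0.92, adjusted p = 0.00135, against 0.74 without), and Chac1, a glutathione-degrading enzyme, 1.89-fold (0.92, adjusted p = 5.77e-05 with the block). The levels of Trib3 varied between replicate numbers within each group: 9.20 ± 0.83 and 10.33 ± 0.83 in wild-type vehicle and rotenone, 8.96 ± 0.92 and 10.02 ± 0.93 in knockout cells, with every pair rising by 1.04 to 1.19. Further named genes that passed only with the block were chosen by the size of their change, not as genes of this response. They were Gadd45a (1.56), Ch25h (1.38), Bhlhe40 (0.88), Noct (0.82) and Gem (0.80) among the rises, and Tubb2b (-0.99), the chaperone gene Hspa1b (-0.83) and Synpo (-0.76) among the falls. Atf4 itself rose by 0.40 (adjusted p = 0.012 with the block, 0.55 without), Asns, asparagine synthetase, by 0.25 (0.045, 0.72) and Mthfd2, a mitochondrial folate enzyme, by 0.38 (0.0039, 0.21). For Gadd45a the pairs numbered 3 gave 0.41 and 0.73, below the other pairs.

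**Figure D3:**
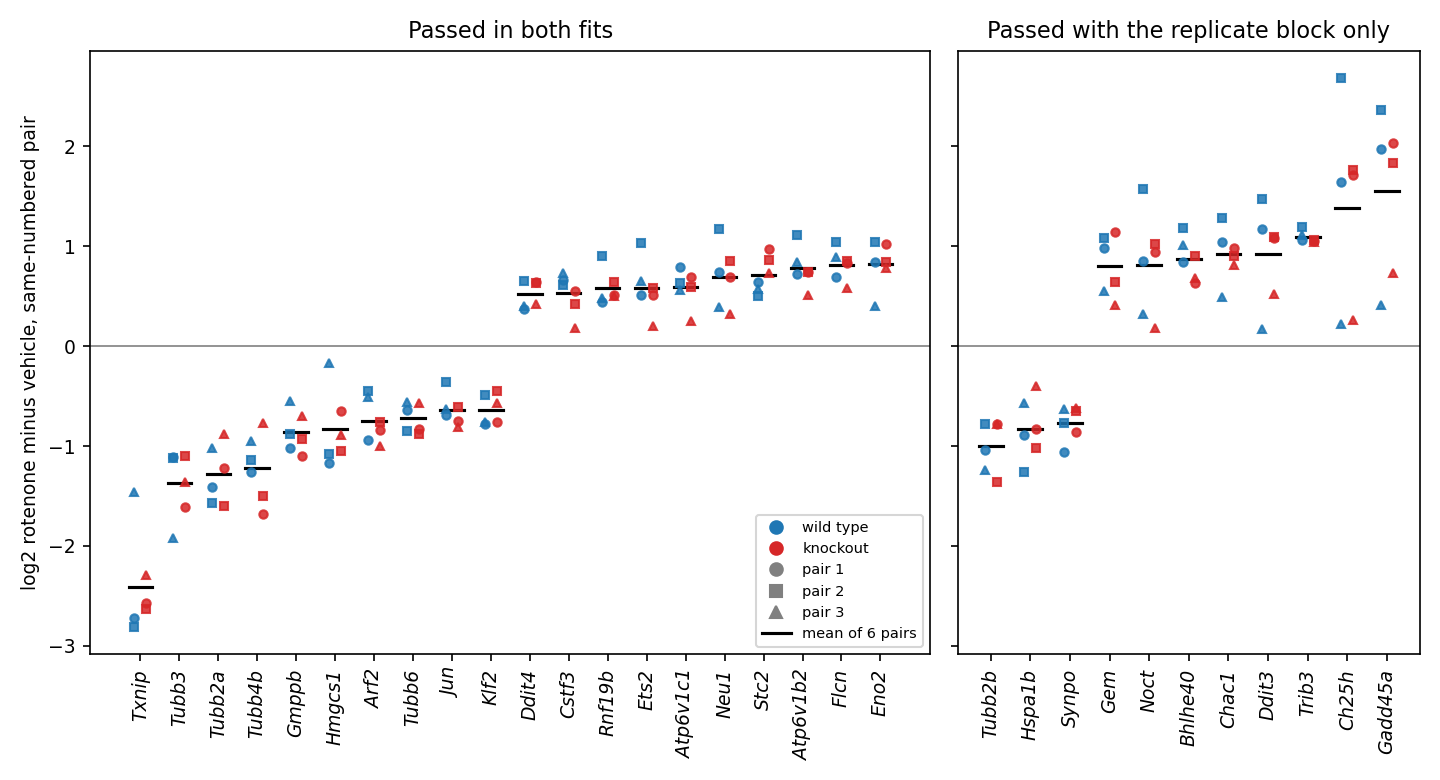
Log2 rotenone minus vehicle difference of same-numbered arrays for the 20 named genes that passed in the mean effect with and without the block and the 11 named genes that passed only with it; each point is 1 pair, with colour for genotype and symbol for replicate number. All points of a gene lie on 1 side of zero, which the rule for naming largely ensured. Averages run from Txnip near -2.41 to Gadd45a at 1.56.

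Read by the fixed gene lists, tubulins and sterol synthesis enzymes were called lower and, at the preset but not at an estimated correlation, the integrated stress response higher. Of 12 tubulin genes, 4 fell, 0 rose and 8 did not pass; adjusted over the list alone 9 fell, and with the block 8 fell. Their median change was -0.67 (camera adjusted p = 1.52e-18; adjusted p = 0.0180 with an estimated correlation). Of 19 sterol synthesis genes, 1 fell, and 7 fell when adjusted over the list alone; with the block 6 fell, among them Stard4 (-0.72), Hmgcs1 and Idi1 (-0.68). All 19 estimates were negative, with a median of -0.21 (adjusted p = 5.00e-15; adjusted p = 0.0180 with an estimated correlation). These were the 2 lists whose call held with an estimated correlation; with both that and the block, the adjusted p was 0.0572 for tubulins and 0.107 for sterol synthesis. Of 26 integrated stress response genes, 2 rose, Ddit4 and Stc2, and 10 rose when adjusted over the list alone; with the block 15 rose. All 26 estimates were positive, median 0.36 (adjusted p = 1.88e-12; adjusted p = 0.328 with an estimated correlation).

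The lists of glycolysis and hypoxia genes were called higher with rotenone at the preset but not at an estimated correlation. Of 19 glycolysis genes, 1 rose (Eno2), 4 adjusted over the list alone, and with the block 3 rose: Eno2, the glucose transporter Slc2a1 (0.53) and hexokinase Hk2 (0.55). Their median was 0.11 (adjusted p = 5.15e-04; adjusted p = 0.458 with an estimated correlation; adjusted p = 0.123 without wild-type rotenone replicate 3). Of 21 hypoxia genes, 1 rose (Ddit4), 3 adjusted over the list alone, and 5 with the block, including Bnip3 (0.72), Kdm3a (0.57) and Vegfa (0.52); the median was 0.11 (adjusted p = 0.00137; adjusted p = 0.109 with an estimated correlation). The 11 genes of serine, one-carbon and proline metabolism all had positive estimates, median 0.21 (adjusted p = 5.63e-05; adjusted p = 0.109 with an estimated correlation). None of them passed singly, 3 rose adjusted over the list alone, and with the block Gpt2 (0.67), Mthfd2 and Shmt2 (0.29) rose. Of 18 cytosolic tRNA synthetases none passed, also over the list alone, and Sars (0.28) rose with the block; the median was 0.17 (adjusted p = 0.00306; adjusted p = 0.328 with an estimated correlation).

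Lists of chaperone, respiratory chain and mitotic genes were called lower at the preset but not at an estimated correlation, with few single calls. Of 18 heat shock genes none passed over all probe sets, and 7 fell adjusted over the list alone (median -0.08, adjusted p = 2.11e-06; adjusted p = 0.109 with an estimated correlation). With the block 5 fell, Hspa1b, Hspa8 (-0.51), Hspa1a (-0.36), Bag3 (-0.35) and Dnajb1 (-0.33), and Hspa4l rose (0.30). The 24 genes of the unfolded protein response of the endoplasmic reticulum had a median of -0.03 (adjusted p = 0.00221; adjusted p = 0.210 with an estimated correlation; adjusted p = 0.0533 without wild-type vehicle replicate 1), with 1 falling over the list alone and Syvn1 (-0.45) and Sdf2l1 (-0.28) falling with the block. None of 33 complex I subunits passed in any of these counts; the median was -0.11 (adjusted p = 5.64e-08; adjusted p = 0.450 with an estimated correlation), but with replicates 1 and 2 alone the adjusted p was 0.148. The 38 subunits of complexes II to V had a median of -0.08 (adjusted p = 5.54e-06; adjusted p = 0.450 with an estimated correlation; 0.111 with replicates 1 and 2 alone). The 24 Hox genes, which mark position in the body, had a median of -0.07 (adjusted p = 1.19e-04; adjusted p = 0.109 with an estimated correlation) and no gene passing. Of 34 genes of the G2 and M phases none passed, and Plk1 (-0.48) fell with the block (median -0.16, adjusted p = 0.00934; adjusted p = 0.933 with an estimated correlation). That call was lost, with adjusted p from 0.158 to 0.752, on leaving out wild-type vehicle replicate 3, wild-type rotenone replicates 1 or 2, knockout vehicle replicate 3, or knockout rotenone replicates 1 or 2, and also without dim probe sets (0.0917). Leaving out 1 array without a block unbalances replicate 3, on which these genes were higher by a median of 1.23. With the block and all arrays the camera adjusted p was 8.34e-08, so such a loss need not mean that the call hung on that array.

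**Figure D4:**
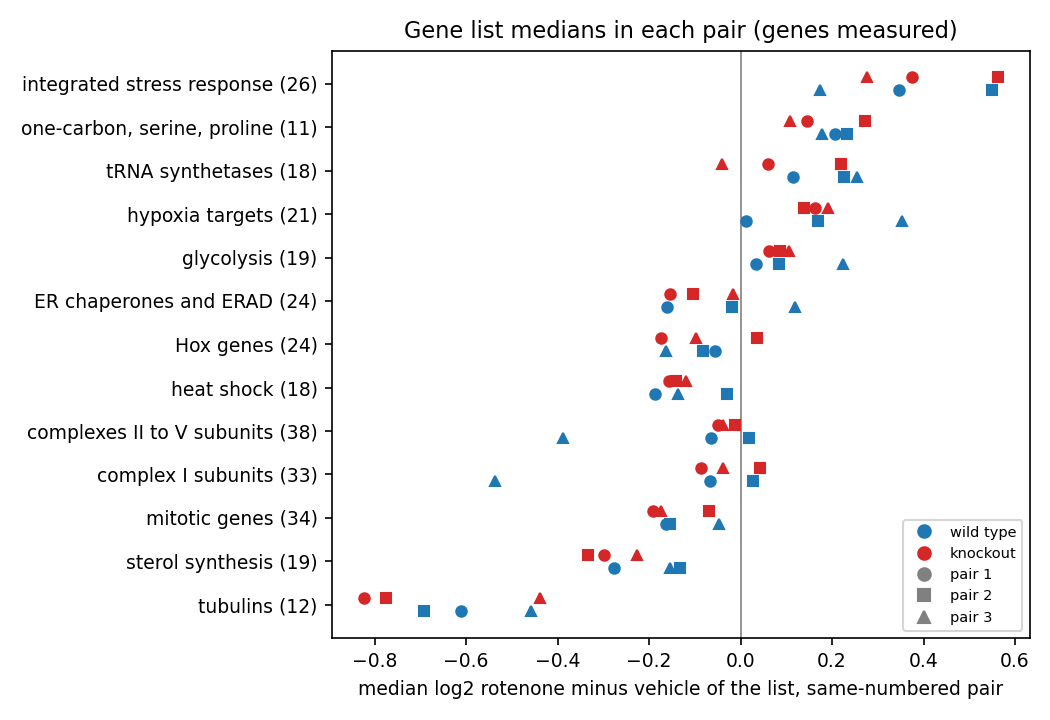
Median log2 rotenone minus vehicle difference of each of the 13 called gene lists, 1 point per same-numbered pair of arrays; colours give genotype and symbols the replicate number. Tubulin medians lie between -0.82 and -0.44 in all 6 pairs, and the complex I median of -0.54 in wild-type pair 3 stands apart from the other 5 pairs.

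The other 26 tested lists were not called in the mean effect. With the block 4 of them became called: fibroblast identity (adjusted p = 0.0827 without and 0.0126 with the block; Pdgfra, a growth factor receptor, fell by 0.62), AMPK and fatty acid genes (0.149, 0.0488; Angptl4 -0.46), senescence (0.196, 0.0390) and G1 and S phase genes (0.381, 0.0332). All 4 were called as lower. In the last list, whose median was -0.05, Cdt1 (0.42) and Pola1 (0.30) nevertheless rose with the block while Rpa2 fell (-0.31). With an estimated correlation and the block none of the 4 was called, the adjusted p being 0.189 for the first 3 and 0.675 for the last. Immediate early genes moved both ways: Jun, Klf2 and Rhob (-0.55) fell, and with the block Egr2 (0.64), Nr4a1 (0.48), Maff (0.47) and Klf4 (0.46) rose and Jund fell (-0.25); adjusted over the list alone 2 rose and 3 fell. As a list they had an adjusted p of 0.478, with a median of 0.02 and a mean of 0.03 although the test pointed down. Single members passed with the block in several more: Pmaip1 (0.63) and Plk2 (0.42) of the p53 list (adjusted p = 0.812), Hmox1 (0.54) of the NRF2 list (0.812), Lif (0.64) of the NF-kB list (0.117), Bid (0.39) of the apoptosis list (0.210), Ifit2 (0.52) of the interferon list (0.625) and Sqstm1 (0.44) of the lysosome list (0.289). Sqstm1 and Bnip3 also belong to the mitochondrial turnover list (0.719), and Neu1, which passed without the block, to the lysosome list. In the list of genes near Htra2 (0.871), Dok1, an adaptor of tyrosine kinases, fell by 0.49 (adjusted p = 0.014).

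For the remaining lists of cell structure and housekeeping the adjusted p was 0.139 for SRF and YAP targets, 0.618 for extracellular matrix (median 0.01, test down), 0.798 for mitochondrial chaperones and proteases, and 0.775 for housekeeping genes; in the last 2 lists the median and mean lay within 0.02 of zero and had opposite signs. NRF2 targets likewise had a median of -0.02 and a mean of 0.02. Markers of other cell types were not called: adjusted p was 0.871 for leukocytes (median 0.01, test down), 0.278 for epithelium, 0.139 for endothelium, 0.719 for neural cells, 0.542 for muscle, 0.618 for cartilage and bone, 0.910 for adipocytes (median 0.02, mean -0.03), 0.680 for erythroid cells and 0.478 for hepatocytes. Of the 15 leukocyte markers 5 lay above the 40th percentile of all probe sets, and no other list held any of them. The lists of mitochondrially encoded genes and of sex chromosome genes had too few measured members for a test. The only member of the former, ND5, changed by 0.07 in wild-type and 0.16 in knockout cells.

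In wild-type cells alone, rotenone lowered Txnip 5.03-fold (log2 -2.33, SE 0.28, adjusted p = 0.024). Flcn was called through a second probe set, and its brightest one stood 1.84-fold higher (0.88, SE 0.12, adjusted p = 0.0517). Tubb2a (-1.33, adjusted p = 0.0517), Klf2 (-0.68, 0.141) and Atp6v1c1 (0.66, 0.158) completed the 5 smallest p-values, and all 5 passed with the block. Without it 3 probe sets passed, 1 higher (Flcn) and 2 lower (both of Txnip), with 986 (2187 with the block) at an unadjusted p under 0.05. With the block 142 passed, 97 higher and 45 lower, but 6, 0 or 370 without replicate 1, 2 or 3. The largest rises then were Gadd45a (1.58), Trib3 (1.12), Bhlhe40 (1.01), Chac1 (0.94), Ddit3 (0.94, adjusted p = 0.031), Atp6v1b2 (0.89), Flcn, Gem (0.87), Atf3 (0.86) and Neu1 (0.77). The largest falls were Txnip, Tubb3 (-1.38), Tubb2a, Tubb4b (-1.12), Tubb2b (-1.02), Hspa1b (-0.90), Synpo (-0.82), Gmppb (-0.82), Hmgcs1 (-0.81) and Tuba1a (-0.75). Atf4 (0.37), Asns (0.29) and Mthfd2 (0.39) did not pass in wild-type cells in either fit, nor did Htra2 (0.02). Without a block the count was 0 when any of wild-type vehicle replicates 1 or 2 or wild-type rotenone replicates 1 or 2 was left out, and 1 without wild-type vehicle replicate 3.

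In these wild-type cells 13 lists were called, 7 higher and 6 lower, of which tubulins (median -0.61, adjusted p = 2.51e-16) and sterol synthesis (-0.17, 9.87e-10) held with an estimated correlation at adjusted p = 0.0456 each; with the block as well, neither did (0.0763 and 0.160). With the block 7 of 12 tubulins fell, 6 of 26 integrated stress response genes rose (median 0.38; adjusted p = 1.70e-08; adjusted p = 0.56 with an estimated correlation) and 2 of 18 heat shock genes fell (median -0.07, 1.74e-04; 0.21 with an estimated correlation). Also lower were complex I (median -0.21, 5.54e-12; 0.43 with an estimated correlation), complexes II to V (-0.15, 7.02e-08; 0.47) and Hox genes (-0.12, 1.35e-04; 0.115), none with a member passing. The complex I median was -0.54 in pair 3, the pair of a rotenone array with the lowest signal of the B1 repeat control (11.7, against 12.4 to 12.7 elsewhere), against -0.07 and 0.03 in pairs 1 and 2; with replicates 1 and 2 alone its adjusted p was 0.25, and that of complexes II to V 0.27. Higher lists were tRNA synthetases (0.22, 1.35e-04), glycolysis (0.09, 4.24e-04), serine and one-carbon genes (0.24, 5.42e-04), hypoxia (0.16, 0.0073), NF-kB targets (0.13, 0.032) and endothelial markers (0.11, 0.032). With an estimated correlation their adjusted p-values were 0.21, 0.56, 0.21, 0.21, 0.63 and 0.615. Glycolysis (0.132 to 0.791) and hypoxia (0.216 to 0.283) were not called without wild-type vehicle replicate 2 or wild-type rotenone replicate 3. Likewise NF-kB targets (0.105 to 0.845) were not called without wild-type vehicle replicates 1 or 2 or rotenone replicate 3, nor endothelial markers (0.140 to 0.555) without vehicle replicates 1 or 3 or rotenone replicate 3. Neither was called without dim probe sets (0.0936 and 0.212). The block ended the endothelial call (0.106) and added G2 and M phase genes as lower (6.11e-05) and lysosome genes as higher (0.024). Neither was called with an estimated correlation (0.611 and 0.625).

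In knockout cells the fall of Txnip was 5.65-fold (log2 -2.50, SE 0.28, adjusted p = 0.0122). The next smallest p-values belonged to Tubb2a (-1.23, adjusted p = 0.124), Jun (-0.72, 0.157), Flcn (0.75, 0.157) and Dok1 (-0.50, 0.311), all of which passed with the block. Without it 2 probe sets passed, both of Txnip, with 829 (1885 with the block) at an unadjusted p under 0.05. With the block 68 passed, 26 higher and 42 lower, but 5, 0 or 343 without replicate 1, 2 or 3. The largest rises with the block were Gadd45a (1.53), Trib3 (1.05), Chac1 (0.90), Eno2 (0.88), Stc2 (0.86), Flcn, Bhlhe40 (0.74), Gpt2, an alanine aminotransferase (0.69), Atp6v1b2 (0.66) and Hs1bp3 (0.60). The largest falls were Txnip, Tubb3 (-1.36), Tubb4b (-1.31), Tubb2a, Tubb2b (-0.97), Gmppb (-0.91), Arf2 (-0.87), Hmgcs1 (-0.86), Ackr3 (-0.76) and Tubb6 (-0.76). Ddit3 was 0.90 higher (adjusted p = 0.056 with the block), and Atf4 (0.43), Asns (0.22), Mthfd2 (0.37) and Htra2 (0.09) did not pass. The count without a block fell to 0 when knockout vehicle replicates 1 or 2 or knockout rotenone replicates 1 or 2 were left out, and was 5 without knockout rotenone replicate 3.

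Knockout cells had 11 lists called, 4 higher and 7 lower. Tubulins (median -0.70, adjusted p = 4.71e-17) and sterol synthesis (-0.25, 4.56e-15) held with an estimated correlation, at adjusted p = 0.0234 and 0.0217; with the block as well, neither did (0.0530 and 0.0831). With the block 7 of 12 tubulins fell and 6 of 26 integrated stress response genes rose (median 0.39, 2.11e-12; 0.36 with an estimated correlation). Lower too were heat shock (-0.15, 2.37e-06), the unfolded protein response (-0.06, 2.78e-04), Hox (-0.045, 0.0077), G2 and M phase (-0.13, 0.021) and complexes II to V (-0.04, 0.046), with adjusted p-values of 0.15, 0.155, 0.19, 0.98 and 0.98 with an estimated correlation. Higher were serine and one-carbon genes (0.19, 3.28e-04), hypoxia (0.11, 0.0036) and glycolysis (0.09, 0.0075), with 0.155, 0.155 and 0.835. Hypoxia (0.0589 to 0.105) and glycolysis (0.257 to 0.413) were not called without knockout vehicle replicate 1 or knockout rotenone replicate 3, nor Hox (0.190) without knockout vehicle replicate 3. Complexes II to V were not called without knockout vehicle replicate 3 or knockout rotenone replicates 1 or 2 (0.115 to 0.919), nor with the block (0.056), without dim probe sets (0.174) or with the mean of a gene's probe sets (0.172). G2 and M phase genes were not called as lower without those same arrays (0.00857 to 0.955), and without knockout vehicle replicate 3 the test turned to higher at 0.00857. Each of these omissions unbalances replicate 3, on which these genes were higher by a median of 1.23. For the same list the camera adjusted p was 9.02e-08 with the block and 0.182 without dim probe sets. With the block, fibroblast identity (0.0061), AMPK and fatty acid (0.037) and G1 and S phase genes (0.0023) were called as lower as well, but none with an estimated correlation (0.153, 0.177 and 0.539).

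Which genes rotenone regulates differently in knockout than in wild-type cells is the question stated for the series. No gene was found to do so: the limma interaction gave 0 probe sets past the threshold with or without the block, and 82 (295 with the block) at an unadjusted p under 0.05, fewer than the 1131 due to chance. So few small p-values may mean that this test calls too little. The simulated arrays held no interaction changes, so its power to find them was not measured. The absence of calls therefore does not show that the genotypes respond alike. The smallest p-values belonged to Lpar3, a lysophosphatidic acid receptor (knockout minus wild-type effect 0.38, SE 0.12, adjusted p = 1.0), Mcoln2 (0.36), Adam2 (0.34), Synj2bp (-0.34) and Uso1 (-0.44). With the block they were Ctnnd1 (0.56), Thumpd3 (-0.44), Serpinb2 (-0.57), Hesx1 (0.40) and Lpar3. For the stress genes the 95% interval of the difference with the block ran from -0.59 to 0.51 for Ddit3, -0.33 to 0.19 for Trib3, -0.27 to 0.39 for Atf4, -0.34 to 0.19 for Asns and -0.28 to 0.25 for Mthfd2. Differences inside these intervals stay open.

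The rotenone effects of the genotypes resembled each other among the called genes. Of the 142 probe sets called in wild-type cells with the block, 141 had the same sign in knockout cells, 135 with an unadjusted p under 0.05, and 50 were called in both, against 0.427 for independent lists. These lists are not independent, because both calls use 1 shared spread per probe set and some genes have several probe sets. The 0.427 is therefore no fair yardstick. Over those 142 the median absolute change was 0.63 in wild-type and 0.49 in knockout cells; over the 68 called in knockout cells it was 0.71 in knockout and 0.63 in wild-type cells. Each set was picked in the genotype in which it is larger. Across all probe sets, which are not independent, the effects correlated at r = 0.588 (Spearman 0.451).

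Only 3 gene lists were called in the interaction. Complex I subunits, called as lower in wild-type but not in knockout cells, differed between the genotypes (median difference 0.16, positive for 30 of 33 genes, adjusted p = 5.61e-06; adjusted p = 0.99 with an estimated correlation), and so did complexes II to V (0.10, 0.0062; 0.99). Cytosolic tRNA synthetases, called as higher in wild-type but not in knockout cells, differed in the other direction (-0.11, 0.028; 0.99). Leaving out 1 array gave 2 to 8 called lists in place of 3. With the block the extracellular matrix list (-0.09, 0.032) was called too, but not with an estimated correlation (0.983). Without wild-type rotenone replicate 3 the adjusted p of complex I was 0.389 and that of complexes II to V 0.429, and replicates 1 and 2 alone gave 0 called lists. The call of complexes II to V was also lost (0.0720 to 0.487) without wild-type vehicle replicates 1 or 3, wild-type rotenone replicate 2, knockout vehicle replicate 2 or knockout rotenone replicate 3. That of tRNA synthetases was lost without dim probe sets (0.0994) and (0.0603 to 0.523) without wild-type vehicle replicates 2 or 3, wild-type rotenone replicates 1 or 2, knockout vehicle replicate 2 or knockout rotenone replicate 3.

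Few single genes were called between knockout and wild-type cells in vehicle. Besides Htra2, the gene with the smallest p was Loxl3, a lysyl oxidase that crosslinks collagen, which lies next to Htra2 in assembly GRCm38.p6. Loxl3 stood at 11.04 ± 0.05 in wild-type and 10.02 ± 0.10 in knockout vehicle cells (SD, n = 3), 2.02-fold lower (log2 -1.02, SE 0.14, adjusted p = 0.16, and 0.0071 with the block). Masp1 (-0.73), Ctsc (0.57) and Hoxd10 (-0.65) followed, each with an adjusted p of 1.0 and not called with the block. Without the block 1 probe set passed, Htra2, and 0 passed when only the arrays compared were fitted. Unadjusted limma p-values under 0.05 were found for 235 probe sets (667 with the block), fewer than the 1131 due to chance. This test may thus call too little, and the simulated arrays held no genotype changes, so few calls do not show few differences. With the block 4 passed, 1 higher and 3 lower, but 1, 1 or 237 without replicate 1, 2 or 3. The 4 were Htra2, Loxl3, Dpt, a matrix protein (0.78, adjusted p = 0.045), and a secondary probe set of Ggct (-0.81), whose brightest probe set was unchanged in estimate (0.01) and which was picked out after its values were seen. With quantile normalization or median-centring, 2 probe sets passed with the block, both lower. Of the 21 genes other than Htra2 with an unadjusted p under 0.001 with the block, 8 (38.1%) lay on the chromosome of Htra2, where 5.85% of all genes lie, Loxl3, Lancl2 and Hoxa9 among them. The stress genes Ddit3 (-0.10), Atf4 (-0.10), Trib3 (-0.24), Asns (-0.13) and Mthfd2 (-0.21) were not called. Leaving out knockout vehicle replicate 3 gave 2 probe sets in place of 1.

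At the preset but not at an estimated correlation, the interferon response list was called higher in knockout vehicle cells and lists of stress, amino acid and mitotic genes lower, without any single member passing apart from those above. The 24 interferon genes had 21 positive estimates and a median of 0.13 (adjusted p = 1.59e-06; adjusted p = 0.19 with an estimated correlation), for example Usp18 (0.33) and Ifih1 (0.31). All 11 serine and one-carbon genes were negative (median -0.18, 2.21e-04; 0.33 with an estimated correlation), as were 25 of 26 integrated stress response genes (-0.11, 2.24e-04; 0.71), with Stc2 (-0.54) and Nupr1 (-0.48), and 33 of 34 G2 and M phase genes (-0.27, 5.11e-04; 0.77), with Cenpf (-0.40) and Aspm (-0.28). Lower as well were NRF2 targets (-0.06, 0.0011; 0.46), genes near Htra2 (-0.05, 0.0011; 0.46; adjusted over the list alone 1 fell, Loxl3), tRNA synthetases (-0.10, 0.0018; 0.46), complex I (-0.05, 0.0034; 0.77), mitochondrial chaperones (-0.04, 0.027; 0.46) and p53 targets (-0.055, 0.039; 0.71). Higher as well were endothelial markers (0.11, 5.11e-04; 0.46), lysosome genes (0.11, 0.0033; 0.68) and cartilage markers (0.06, 0.048; 0.50), of which the block ended the last (0.085). In these parentheses the values are the median, the adjusted p and the adjusted p with an estimated correlation, which ended all 13 calls.

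Of these 13 calls, those of interferon and of serine and one-carbon genes held on leaving out any of the 6 arrays. Leaving out wild-type vehicle replicate 1 or knockout vehicle replicate 3 ended those of the integrated stress response (adjusted p 0.156 to 0.237) and tRNA synthetases (0.0520 to 0.0830). Wild-type vehicle replicate 1 or knockout vehicle replicate 2 ended that of NRF2 targets (0.111 to 0.127), and these or wild-type vehicle replicate 3 that of complex I (0.312 to 0.611). Wild-type vehicle replicate 3 or knockout vehicle replicates 1 or 2 ended that of G2 and M phase genes (0.577 to 0.856), these or wild-type vehicle replicate 1 that of mitochondrial chaperones (0.229 to 0.627), and wild-type vehicle replicate 2 or knockout vehicle replicates 1 or 2 that of lysosome genes (0.128 to 0.410). Such omissions unbalance replicate 3, where G2 and M phase genes were higher (median 1.23) and integrated stress response genes lower (-0.47). With the block and all arrays the camera adjusted p-values of these lists were 1.10e-19 and 2.45e-07. Loss of a call on leaving out 1 array thus need not mean that it hung on that array. The p53 call ended without wild-type vehicle replicates 1 or 2 or knockout vehicle replicate 3 (0.0536 to 0.773), and the cartilage call without replicates 1 or 3 of either group (0.154 to 0.369). Endothelial markers were not called without wild-type vehicle replicate 3 (0.0595), nor genes near Htra2 without knockout vehicle replicate 3 (0.114). The calls of mitochondrial chaperones, p53 targets and cartilage markers also ended without dim probe sets (0.0989, 0.306 and 0.214) and with the mean of a gene's probe sets (0.0567, 0.0666 and 0.0732). With the block, G1 and S phase (1.16e-05), hypoxia (0.031) and apoptosis genes (0.043, a list that holds Htra2 itself) were added as lower, none of them called with an estimated correlation (0.468 each).

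**Figure D5:**
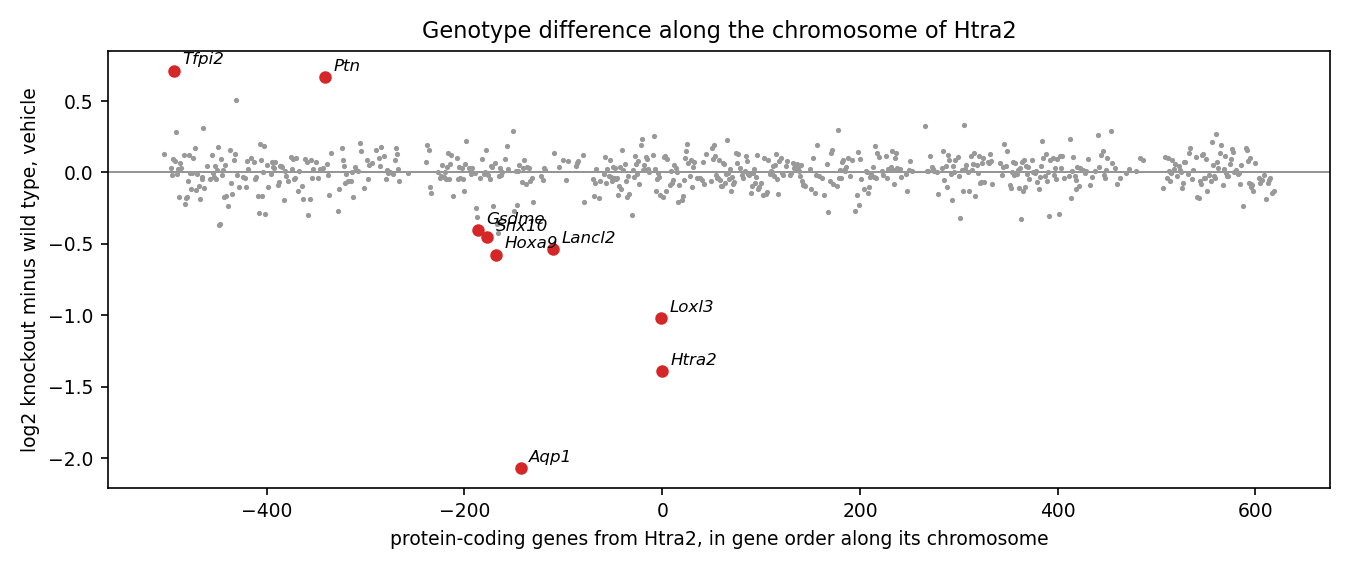
Log2 knockout minus wild-type difference in vehicle of the measured genes on the chromosome of Htra2, against the number of gene positions from Htra2 in assembly GRCm38.p6. Htra2 (-1.39) and its neighbour Loxl3 (-1.02) lie together at the origin, and Aqp1 (-2.07) lies 143 positions before them.

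In rotenone, Htra2 and Loxl3 again had the smallest p-values for genotype. Loxl3 was 2.04-fold lower in knockout cells (log2 -1.03, SE 0.14, adjusted p = 0.141, and 0.0061 with the block). Also among the 5 smallest p-values, with the block or without it, were En1, a homeobox gene (0.83, from 5.93 ± 0.18 to 6.77 ± 0.22), Masp1 (-0.88), Lancl2 (-0.77) and Hoxa9 (-0.78). None of these 4 passed without the block, and all passed with it, at adjusted p = 0.046, 0.026, 0.010 and 0.026. Without the block 1 probe set passed, Htra2, with 1260 (2938 with the block) at an unadjusted p under 0.05. With the block 9 passed, 1 higher and 8 lower, but 0, 1 or 347 without replicate 1, 2 or 3, and 6, all lower, with median-centring. Ddit3 (-0.14), Atf4 (-0.05), Trib3 (-0.31), Asns (-0.20) and Mthfd2 (-0.23) were not called. The count was 0 without wild-type rotenone replicates 1 or 3 or knockout rotenone replicate 1. Across probe sets, which are not independent, the genotype differences in vehicle and in rotenone correlated at r = 0.556.

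In rotenone 3 lists were called, with no member but those above passing: tRNA synthetases (median -0.17, adjusted p = 1.77e-05; adjusted p = 0.39 with an estimated correlation), interferon genes (0.18, 1.77e-05; 0.33), of which 2 rose adjusted over the list alone, and G2 and M phase genes (-0.27, 0.034; 0.84). The last was not called without wild-type rotenone replicate 3 or knockout rotenone replicates 1 or 2 (0.573 to 0.816), nor without dim probe sets (0.203). Omitting 1 of these arrays unbalances replicate 3, on which the G2 and M phase genes were higher. Their camera adjusted p with the block and all arrays was 3.18e-11. With the block 7 lists were called, the added ones, all lower, being serine and one-carbon (0.0021), NRF2 (0.049), p53 (0.0089) and G1 and S phase genes (1.05e-06). None of these was called with an estimated correlation (0.438, 0.817, 0.778 and 0.438). Leaving out any 1 array gave 6 to 10 called lists in place of 3.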

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

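The test of a single array and the fit of replicates 1 and 2 alone were chosen only after the result was seen; the test of ribosomal protein genes was planned before its result was known. In the interaction, 3 gene lists differed between genotypes: complex I subunits (median difference in the rotenone effect, knockout minus wild type, 0.161 on the log2 scale), subunits of complexes II to V (0.10) and cytosolic tRNA synthetases (-0.105). Their adjusted p-values were 5.61e-06, 0.00619 and 0.0283 with camera's preset correlation and 0.989 each with an estimated one.

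For the respiratory chain genes, a single array, wild-type rotenone replicate 3, is a candidate source. Without it the adjusted p of complex I was 0.389, within a range from 1.11e-13 to 1.0 over all alternatives, and its median difference dropped from 0.16 to 0.02. The median difference of complexes II to V dropped from 0.10 to 0.03. In the pair with that array the 42 genes of cytosolic ribosomal proteins, which are short and abundant as well, had a median difference of -0.228, against 0.0128 to 0.0299 in the other 5 pairs, as a loss of short abundant transcripts on that array would give. In pairs 1 and 2 the complex I medians were -0.07 and 0.03 in wild-type and -0.09 and 0.04 in knockout cells. Those of complexes II to V were -0.06 and 0.02 in wild-type and -0.05 and -0.01 in knockout cells. The biological explanation that the design offers is a weaker response of these genes in knockout cells. Pairs 1 and 2 show none, but without a clear fall in wild-type cells there they cannot decide on it. For pair 3 such a response cannot be told apart from a fault of that array.

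Among the smallest interaction p-values, 4 genes had all 3 pairs of one genotype moving up and all 3 of the other moving down: Lpar3 (0.38, knockout minus wild type), Adam2 (0.34), Hesx1 (0.40) and Thumpd3 (-0.44). Lpar3, Adam2 and Hesx1 were higher with rotenone in knockout and lower in wild-type cells, and Thumpd3 the reverse. The interaction adjusted p was 1.0 for each, so the differences did not pass the test.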

How the results depend on the processing

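Only the plan for the counts without a block predates the data; alternatives for the blocked counts, replicates 1 and 2 alone and the genotype and number block were added after the results were seen. Htra2 stayed lower in knockout vehicle cells on leaving out an array, from -1.51 to -1.26. It did not pass when only the arrays compared were fitted (0 probe sets called) or as the mean of its probe sets (-0.50), and the dimmer probe set alone had the opposite sign (0.40); the cause was not tested. The interaction gave 0 probe sets under every alternative that was run for it. The genotype and number block and the alternatives for the blocked counts were not run for the interaction. A change of pseudocount was not run, since the values are already log2. At the preset correlation, the replicate block changed no other list call than those printed beside the results. Depth in the sense of signal over background is unknown for these values.

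Array weights raised the counts without a block to 2 (genotype in vehicle, from 1), 11 (rotenone in wild type, from 3), 53 (rotenone in knockout, from 2), 2 (genotype in rotenone, from 1) and 346 (mean effect, from 49). The replicate block gave 4, 142, 68, 9 and 557 in the same order, and replicates 1 and 2 alone 90, 122, 85, 129 and 506. Taking the mean of a gene's probe sets, with fewer features tested, gave 0 for either genotype comparison and 27 for the mean effect. Only the arrays compared gave 0, 1 and 0 for genotype in vehicle and rotenone in wild type and knockout, with fewer arrays behind the spread. Leaving out dim probe sets gave 5 for rotenone in wild type, and a 1.5-fold minimum 27 for the mean effect. Leaving out 1 array gave 1 to 2, 0 to 2, 0 to 5, 0 to 1 and 7 to 68 in the order above.

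For the blocked counts, genotype in vehicle went from 4 to 2 without dim probe sets, with quantile normalization or with median-centring, and to 7 with array weights. Rotenone in wild type went from 142 to 217 with array weights and 313 with the genotype and number block, rotenone in knockout from 68 to 810 and 166, and the mean effect from 557 to 1220 and 968. Genotype in rotenone went from 9 to 5 with quantile normalization and to 254 with weights. Without the 4 arrays of 1 replicate number the ranges were 1 to 237, 0 to 370, 0 to 343, 0 to 347 and 44 to 1054, each highest without replicate 3.

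Lists called fell from 13 to 0 (genotype in vehicle), 13 to 2 (rotenone in wild type), 11 to 2 (rotenone in knockout), 3 to 0 (interaction), 3 to 0 (genotype in rotenone) and 13 to 2 (mean effect) with an estimated correlation, and with fry to 0, 0, 2, 0, 0 and 3. Combined with the block, an estimated correlation called 0 lists in all 6 comparisons and fry 0, 4, 6, 0, 0 and 8. The interaction had 0 with replicates 1 and 2 alone. Genotype in rotenone had 6 with the mean of probe sets, 7 with the block and 9 with replicates 1 and 2 alone. Leaving out an array gave 9 to 17, 13 to 15, 10 to 13, 2 to 8, 6 to 10 and 12 to 15. Quantile normalization turned the median of no called list. Unless a reason is given, the cause of a shift was not tested. Of 456 values of 42 named gene results with 1 array left out, 323 kept their side of the threshold, 130 no longer passed, 3 newly passed and 0 reversed.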

Other observations

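Tests of the chromosome of Htra2, RNA integrity and leukocytes were chosen only after the result was seen; those of embryo sex, of single probe sets and of other splits were planned before. Subunits of the lysosomal proton pump were looked at after 2 of them were seen among the largest rises that passed without the block. Of 21 measured genes of the pump, 5 rose in the mean rotenone effect with the block: Atp6v1b2 (0.78), Atp6v1c1 (0.59), Atp6ap2 (0.40, adjusted p = 0.010), Atp6v1d (0.38, 0.0413) and Atp6v1a (0.34, 0.0455). Without the block 2 passed, Atp6v1b2 and Atp6v1c1. The arrestin gene Arrdc4, like Txnip a target of glucose-sensing transcription factors, fell on both of its probe sets (-0.57, adjusted p = 0.0180, and -0.89, adjusted p = 0.0415), and a second Txnip probe set fell by 1.93 (adjusted p = 2.17e-04).

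The arrays numbered 3 differed from the others in growth and stress genes in all 4 groups. G2 and M phase genes were higher by a median of 1.23, with 33 of 34 called (adjusted p = 6.65e-39; adjusted p = 0.066 with an estimated correlation), and G1 and S phase genes by 0.96 (30 of 31 called; 1.11e-33; 0.028). NF-kB targets were higher too (0.66; 1.81e-10; 0.028), and integrated stress response genes lower (-0.47, 21 called lower; 3.85e-12; 0.17). The cell cycle inhibitor Cdkn2a was lower by -2.12 on the log2 scale, and Trib3 by -1.52. Xist was higher (1.78) and the Y-linked genes Eif2s3y (-1.57) and Uty (-0.69) lower, while Kdm5d, also Y-linked, did not pass (-0.19, adjusted p = 0.102).

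For this difference of replicate 3, embryos of another sex may play a part, but sex alone would place most called probe sets on X or Y, and 3.91% of 4547 lay there, against 3.35% of all. Degraded RNA would raise the signal at the 3' end over the 5' end; the Gapdh difference averaged 0.0618 on these arrays, inside the range of -0.062 to 0.126 of the others, and those of beta-actin (-0.047) and pyruvate carboxylase (0.533) lay inside theirs. That of the transferrin receptor averaged 2.60, above the range of 2.25 to 2.48 of the others, so degradation stays open. Leukocytes may also have contributed: 10 of 15 markers were called higher (adjusted p = 8.90e-06; 0.174 with an estimated correlation), Lyz2 by 2.26, Cd68 by 0.53 and Tyrobp by 0.49, and the median of 0.268 over the 14 markers other than Lyz2 decides nothing, because only 4 of them lay above the 40th percentile of all probe sets. The rise was not particular to leukocytes. Of 19 muscle markers 8 were called higher (camera adjusted p = 1.41e-05, and 0.174 with an estimated correlation), and of 8 adipocyte markers 3 (0.0228 and 0.213). Another preparation of cells, culture day or processing batch stays open, because the labels give none of these.

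In vehicle, the genes with the smallest unadjusted p-values for genotype gathered on the chromosome of Htra2, although most of them did not pass the threshold. Of 21 genes with an unadjusted p under 0.001 with the block in vehicle, Htra2 left out, 8 lay on chromosome 6 (38.1%, against 724 of 12368 genes, 5.85%; odds ratio 9.99, 95% interval 3.58 to 26.1, Fisher's exact two-sided p = 1.36e-05). In assembly GRCm38.p6 they lie 1 (Loxl3), 110 (Lancl2), 143 (Aqp1), 168 (Hoxa9), 177 (Snx10), 186 (Gsdme), 341 (Ptn) and 494 (Tfpi2) gene positions before Htra2, and they were picked by this p. Aqp1, a water channel, had estimates of -2.07 in vehicle and -1.94 in rotenone. It was called in neither (limma unadjusted p = 2.54e-05 and 4.95e-05 with the block).

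Whether DNA of another strain carried along with the targeted locus accounts for part of these differences stays open: the odds ratio of 9.99 was not shared by the genes of the mean rotenone effect (14 of 274, 5.11%; odds ratio 0.863, interval 0.463 to 1.49, Fisher's exact p = 0.696). In rotenone the genotype genes gave 8 of 78 (10.3%; odds ratio 1.85, interval 0.765 to 3.86, Fisher's exact p = 0.138), an interval that reaches below 1. Nearness to Htra2 did not settle it, because among 49 measured genes within 30 positions only Loxl3 had such a p (the next smallest was 0.0267), against 7 of 644 farther away (odds ratio 1.89, interval 0.0412 to 15.2, Fisher's exact p = 0.446). Whether strain variants under single probe sets play a part could not be settled, because 4 of the genes had another probe set, whose median difference was 42.8% of the first. An effect of HtrA2 loss on these genes stays open and untested.

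Other splits of the arrays were counted for each result. For each comparison of 3 against 3 arrays there are 10 splits, too few for a share under 0.05. The real counts were 1, 3, 2 and 1 for genotype in vehicle, rotenone in wild type, rotenone in knockout and genotype in rotenone, and the highest other count was 0, so 1 of 10 splits, the real one, gave as many. For the mean rotenone effect, 2 of 100 relabellings of treatment within genotype, the real one included, gave 49 or more. Relabellings that part fewer same-numbered pairs than the real one are not a like comparison, so this share does not exclude chance. The other relabelling of these 2 called 106 probe sets and parted only 2 of the same-numbered pairs. A relabelling of this kind can put all arrays numbered 3 on 1 side, but which arrays it grouped was not examined. The others drawn that parted 2 pairs gave 0. Splits parting all 6 pairs, like the real one, gave at most 0. A count of 0, as in the interaction, is met by all 100 of 100 relabellings whatever the data, so this tells nothing about chance; the highest of them gave 3.

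Assignments within same-numbered pairs were used for the blocked counts. In each comparison of 3 pairs only 4 assignments exist, too few for a share under 0.05: the real counts were 4, 142, 68 and 9, 1 of 4 assignments in each case, and the highest other count was 0. For the mean effect 1 of 32 assignments, the real one with 557 probe sets, gave as many, and the highest other gave 0. That share lies under 0.05 but is the smallest that 32 assignments can give. It also rests on a pairing that was read from the same data, so chance is not excluded.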
